A study of Caenorhabditis elegans with 10 samples.

How the data were processed

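Whole-animal RNA of a Caenorhabditis elegans him-5 strain was sequenced from 10 samples, 1 hermaphrodite and 1 male sample at each of 5 windows after hatching. Per the labels' protocols, animals were grown at 20 °C on agar plates with OP50 bacteria, and total RNA was taken with TRIzol. The deposited values are raw read counts per gene, made with CASAVA 1.8 and HTSeq per the submitters' processing notes. The aligner, the genome build, the HTSeq version and the use of strand are not given in the sources used here. Each count table lists 46589 genes by sequence name and 5 totals that name no gene, which were left out of library sizes and tests. As a share of all reads, these totals were 2.18% to 3.98% for reads on no feature, 0.32% to 0.75% for ambiguous reads, 3.31% to 25.38% for reads not aligned and 11.23% to 17.83% for reads aligned to several places. Reads aligned to several places were given to no gene, so near-identical copies, such as the major sperm protein genes, and overlapping or antisense genes are read with uncertainty.

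Names and positions came from the Ensembl annotation of the assembly WBcel235, in which 46180 of the sequence names were found and 409 were not. Where several genes share a symbol (1312 of them), the sequence name is given. Coordinates count from 1. Gene reads per library were 9490350, 8233794, 8189325, 18480591 and 17816317 in hermaphrodites and 10742873, 27907544, 18400589, 12364394 and 11902852 in males, in order of time. Of gene reads, ribosomal RNA genes held 5.34%, 6.72%, 9.63%, 10.96% and 11.27% in hermaphrodites in order of time and 4.62% to 8.62% in males. Mitochondrial genes held 7.06%, 11.14%, 5.79%, 3.9% and 3.39% in hermaphrodites and 6.61% to 10.89% in males. The ribosomal RNA share in hermaphrodites was thus higher at each later window, which the slope test cannot separate from the age of the animals. Without these genes, 6002 slopes were called in hermaphrodites. No pair of libraries agreed within sampling noise.

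The groups, the comparisons and their tests, the gene lists and the rule for naming genes were fixed before the data were examined. So were the alternatives, except for leaving out ribosomal RNA and mitochondrial genes and leaving out the male library of 42 to 46 h or of 54 to 58 h, which were chosen after seeing the data. The tests of RNA from the other sex, of older males and of shared reads were also chosen after the result was seen. Genes with at least 1 CPM in at least 2 libraries (15924) were tested with TMM scaling in edgeR 4.0.16 (quasi-likelihood test, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The sex difference over 5 time points had time point as a block (4 residual degrees of freedom). The slopes per 6 h step in each sex came from 1 fit to all 10 libraries (6 degrees of freedom), and their difference from a fit with time point as a block (3). The young adult comparison set 2 libraries per sex against each other (2). Errors after ± are approximate standard errors unless SD is named. Each is the size of the log2 value divided by the square root of the test's F statistic, not an error estimated by the fit. Log2 ratios are male over hermaphrodite. Single windows were compared by size alone, as at least 4-fold on CPM + 1 with at least 5 CPM in the higher library. Nothing in the labels says that libraries came from separate cultures, so p-values measure only the spread between these samples, which here includes the change between time points.

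Lists of 26 gene groups were counted and tested with camera in limma 3.58.1, with the inter-gene correlation preset at 0.01 and, as an alternative, estimated. They comprised yolk proteins, major sperm proteins, other sperm genes, male gonad secretion, oocyte and eggshell, shared germline, male sensory neurons, male tail, sex determination, vulva and egg laying, embryonic regulators, molting, heterochronic regulators, adult, structural and all collagens, muscle, intestine, DNA replication, ribosomal proteins, histones, neuropeptides, C-type lectins, chemoreceptors, nuclear hormone receptors and hedgehog-related proteins. The named genes are the 6 largest called changes in each direction with a mean of at least 5 CPM and, for sex differences, 1 direction throughout, then up to 3 called members per list by size, or the most abundant member of a list with none called, and at single windows the 3 highest and 3 lowest ratios. Some genes that this rule names are not reported here. Genes known to mark sex were also read as a check of the labels. A fold against a group with 0 reads was computed against 3 reads over the group. With 1 to 3 reads the ratio is given with a 95% exact binomial interval, and floors and intervals cover counting error only. X-linked and autosomal genes were compared with an exact sign-flip test over the 5 time points.

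Alternatives were RLE factors, library size only, DESeq2 1.42.0, limma-voom, other filters, a robust prior, other thresholds, fits without or with a block, fits to 1 sex or stage alone, and leaving out each time point or library. On simulated counts with 200 changed genes, the test of sex over 5 time points called 6.25%, 54.9% and 90.8% of changes of 2-fold, 4-fold and 8-fold, with 3 false calls. The tests of slope in hermaphrodites and males called 21.7% and 20.4% of 8-fold changes over the course, the test of the slope difference 18.9%, and the young adult test 92.4%. The adjustment depends on how many genes change, here 200 of 15924, so these shares need not hold in the data. Time points served as pairs of the sexes: the deviations of same-time libraries from their group means correlated at 0.416, 0.419, 0.326, 0.406 and 0.243. The highest correlation with a library of another time was 0.33, 0.33, 0.179, 0.418 and 0.418, above the same-time value at the last 2 time points. Figures were drawn with matplotlib 3.10.9.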

Results

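The transcriptomes of whole Caenorhabditis elegans were measured by RNA sequencing in a him-5 strain, a mutant background in which X chromosome loss yields many males. Hermaphrodites, which make a limited number of sperm and then oocytes, and males, which make sperm only, were collected at 5 windows after hatching: 30 to 34 h (late L3 larvae), 36 to 40 h (early L4), 42 to 46 h (late L4), 48 to 52 h (young adults) and 54 to 58 h (young adults). Each sex had 1 library per window, 10 libraries in all, so no sex and time point was replicated and each test below takes its error from the spread across time points. Reads assigned to genes ranged from 8189325 (hermaphrodite, 42 to 46 h) to 27907544 (male, 36 to 40 h). The share of reads not aligned was 25.38% in the male library of 54 to 58 h, against 3.7% to 5.58% in the other male libraries. Of 46589 genes listed, 15924 had at least 1 CPM on library size only in at least 2 libraries and were tested. CPM values given below are TMM-scaled read counts relative to library size.

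Genes with known sex-specific expression mostly followed the labels. The DM-domain transcription factor gene mab-3 had 17.2 to 34.5 CPM in the 5 male libraries and 0.114 to 2.09 CPM in the 5 hermaphrodite libraries. The polycystin gene pkd-2, expressed in male sensory neurons, had 0.87 CPM at 30 to 34 h and 47.9 CPM at 54 to 58 h in males, and at most 0.417 CPM in hermaphrodites. The yolk protein gene vit-2 reached 9180 CPM in hermaphrodites at 54 to 58 h, against 90.8 CPM in males. The male-determining gene her-1 had 8.23 to 21.3 CPM in males, and 0 to 1.25 CPM in hermaphrodites except at 54 to 58 h, where it had 7.16 CPM. The oocyte yolk receptor gene rme-2 reached 1310 CPM in hermaphrodites and 81.4 CPM in males. At 30 to 34 h, though, rme-2 had 158 reads in the hermaphrodite and 272 in the male library. The sex-determination gene tra-1 had 40 to 112 CPM in hermaphrodites and 61.6 to 138 CPM in males. The gene xol-1 had no more than 2.96 CPM in any library, with 28 reads in hermaphrodites and 18 in males at 54 to 58 h.

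**Figure D1:**
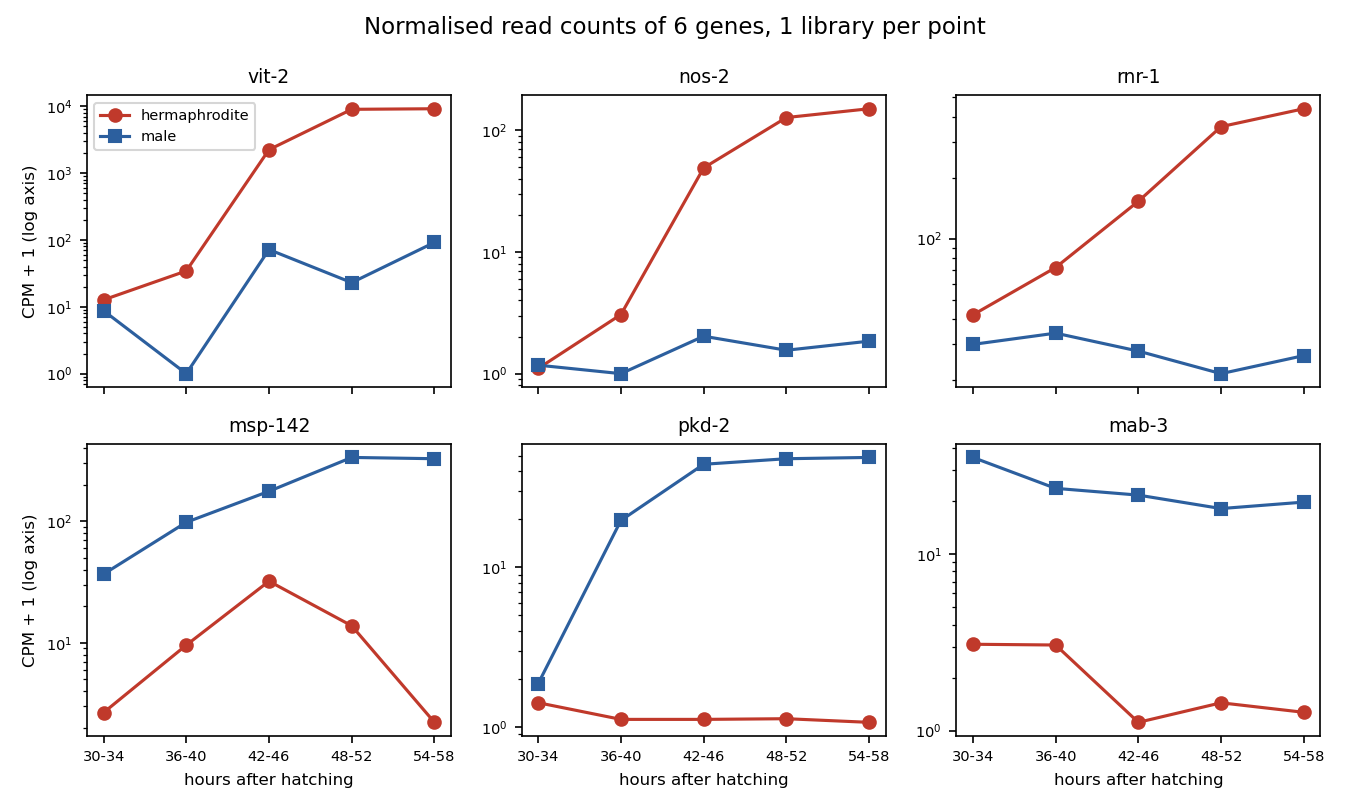
Normalised read counts (CPM + 1, log axis) of 6 genes against hours after hatching, in hermaphrodites (red circles) and males (blue squares), with 1 library per point and no error bars. In hermaphrodites vit-2, nos-2 and rnr-1 reached 9180, 149 and 438 CPM at 54 to 58 h, while msp-142, pkd-2 and mab-3 were higher in the male library at each of the 5 windows.

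The first comparison asked which genes differed between the sexes over the whole course. Higher in males were 30 of 34 major sperm protein genes, 30 of 36 other sperm genes, 7 of 13 genes of male sensory neurons and 57 of 152 C-type lectin genes. Higher in hermaphrodites were 6 of 6 yolk, 13 of 40 oocyte, 8 of 26 DNA replication and 21 of 75 ribosomal protein genes (with library size only 8 oocyte and 5 DNA replication genes). No list was called by camera with an estimated correlation (adjusted p = 0.257 for male sensory neurons and 0.451 for the others named here). In edgeR's quasi-likelihood test with time point as a block (n = 5 libraries per sex), 3003 genes passed an adjusted p of 0.05, of which 2436 were higher in males and 567 higher in hermaphrodites. The split was 3985 to 1935 with DESeq2, 3418 to 1840 with limma-voom, 2450 to 1527 without time as a block and 1135 to 708 without the 30 to 34 h pair. Of the 3003 genes, 2811 kept 1 direction at all 5 windows. The median log2 ratio of all tested genes was 0.21 towards males under TMM, 0.17 with RLE factors and 0.32 with library size only. It was 0.03 without the 42 to 46 h or the 48 to 52 h pair, 0.02 without the 54 to 58 h pair or the male library of 54 to 58 h alone, 0.13 without time as a block, -0.00239 with at least 5 CPM in 5 libraries and 0.36 without a filter, so the shift depended on the libraries, the fit and the filter. Only 144 genes passed an adjusted p of 0.01. The count was 237 without the 42 to 46 h pair of libraries, 118 without the 48 to 52 h pair, 1843 without the 30 to 34 h pair, 311 without the male library of 42 to 46 h and 1881 without that of 54 to 58 h, and every gene left without the 42 to 46 h or the 48 to 52 h pair was among the 3003.

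Sex differences were ranked among called genes with a mean of at least 5 CPM and 1 direction throughout. The 6 genes with the largest male excess over the course had 0 or 1 read in all hermaphrodite libraries together. W02D7.12 (chromosome V, 8311510 to 8312090) had 2115 male reads and none in hermaphrodites, which makes it at least 490-fold higher in males against a floor of 3 reads over the hermaphrodite group. By the same floor, ZC204.17 was at least 285-fold, nas-40 (annotated as a pseudogene) at least 276-fold, C35B1.3 at least 257-fold and F13E9.19 at least 242-fold higher. The gene srlf-26 had 2497 male reads and 1 hermaphrodite read, a ratio of 1730 (95% exact binomial interval 311 to 68500, counting error only). On the hermaphrodite side, F40G12.11 had a log2 ratio of -6.92 ± 0.84 (SE, n = 5 per sex, adjusted p = 0.00666), D1086.7 of -6.59 ± 0.99, D1086.10 of -6.54 ± 0.83, ule-2 of -6.40 ± 1.21, Y51H7C.13 of -6.24 ± 1.02 and vit-2 of -6.23 ± 1.44 (adjusted p = 0.031). D1086.7 and D1086.10 both lie on chromosome V (14084270 to 14085811 and 14082753 to 14083584).

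All 6 yolk protein genes were lower in males, with log2 ratios of -6.23 for vit-2, -5.54 ± 1.18 for vit-6 and -5.48 ± 1.24 for vit-5. Of 34 major sperm protein genes, 30 were higher in males and none lower, and 34 passed when p was adjusted over the list alone. They included msp-74 (log2 5.19 ± 1.15), msp-142 (4.45 ± 0.78) and msp-42 (4.21 ± 1.09), the last annotated as a pseudogene. These genes are near-identical copies, so their single values are uncertain. In the list of 36 other sperm genes, 30 were higher in males and none lower (35 adjusted over the list alone), led by ssp-19 (log2 4.29 ± 0.96) and ssp-10 (4.25 ± 0.90). The seminal fluid protease gene try-5 (4.28 ± 1.19) and the sperm activation gene snf-10 (3.96 ± 0.88) were 2 of 3 genes called in the list of male gonad secretion (1 with library size only). Among 40 oocyte and eggshell genes, 13 were lower in males and none higher (32 adjusted over the list alone). The nanos relative nos-2 had a log2 ratio of -6.39 ± 1.06, and the eggshell genes perm-4 and perm-2 had -4.67 ± 1.02 and -4.65 ± 0.74. Of 46 germline and meiosis genes shared by both sexes, 4 were lower in males (1 adjusted over the list alone), among them gld-1 (-2.09 ± 0.53), pgl-1 (-1.36 ± 0.26) and fbf-1 (-1.09 ± 0.28). In the male libraries of 42 to 46 h and 54 to 58 h, 20 other hermaphrodite-biased genes were read at a median of 3.43% and 1.76% of their hermaphrodite level, and the yolk genes at a median of 4.5% and 1.25%.

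Of 13 genes of male sensory neurons, 7 were higher in males and none lower. Among them, cwp-2 had 1369 male and 3 hermaphrodite reads (ratio 317, interval 108 to 1540), cwp-1 had 830 and 3 (ratio 192, interval 65.5 to 934), and cwp-3 was at least 38.9-fold higher with 168 and 0. The polycystin genes pkd-2 and lov-1 had log2 ratios of 7.11 ± 1.28 and 6.03 ± 1.08. Of 20 male tail and development genes, 5 were higher and none lower (adjusted p = 0.0654 with the preset correlation in camera), led by the DM-domain genes dmd-3 (6.22 ± 0.997) and mab-3 (5.0 ± 0.63) and by mab-23 (4.72 ± 0.98). In the list of 23 sex determination and dosage compensation genes, 3 were higher and 1 lower in males, and camera's direction for the list was lower (adjusted p = 0.0285 with the preset correlation, 0.667 with an estimated correlation). The 3 were fog-3 (4.28 ± 0.83) and fog-1 (1.64 ± 0.35), needed for sperm fate, and her-1 (4.15 ± 1.20). Neuropeptide and insulin-like genes were called higher in males for 17 of 113 and lower for none (with RLE factors 1 was lower, and with library size only 11 were higher). The FMRFamide-like gene flp-23 had 777 male reads and 1 hermaphrodite read (ratio 540, interval 96.6 to 21300), and ins-31 had a log2 ratio of 7.71 ± 1.15. Of 152 C-type lectin genes, 57 were higher and 5 lower in males. clec-130 was at least 89.4-fold higher, and clec-96 had a log2 ratio of 9.38 ± 0.60 (adjusted p = 0.00051).

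Of 26 DNA replication genes, 8 were lower in males and none higher (19 adjusted over the list alone), led by the ribonucleotide reductase gene rnr-1 (-2.48 ± 0.64) and the helicase gene mcm-5 (-2.32 ± 0.56). Of 75 ribosomal protein genes, 21 were lower and none higher (68 adjusted over the list alone), with rpl-28 at -1.51 ± 0.34. Of 34 histone genes, 4 were lower (2 with library size only) and 1 higher. The exception, his-70, had a log2 ratio of 3.62 ± 0.85, and his-8 had -3.21 ± 0.85. Of 24 muscle genes, only the troponin I gene tni-3 was called, with 3.22 ± 0.66. Camera, limma's competitive gene set test, called 18 of the 26 lists with the inter-gene correlation preset at 0.01. None was called with an estimated correlation. The adjusted p was then 0.257 for male sensory neurons, 0.451 for the yolk, both sperm, male gonad secretion, oocyte, DNA replication, ribosomal, histone and C-type lectin lists, 0.462 for the shared germline list, 0.496 for neuropeptides, 0.549 for muscle and 0.667 for sex determination.

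At single windows, where 1 library stood against 1 and no test was possible, the number of genes at least 4-fold apart (log2 of CPM + 1, with at least 5 CPM in the higher library) was 1068 at 30 to 34 h, 888 at 36 to 40 h, 1786 at 42 to 46 h, 3177 at 48 to 52 h and 3772 at 54 to 58 h. Males were the higher sex for 1032, 800, 1516, 2392 and 2640 of these, and hermaphrodites for 36, 88, 270, 785 and 1132. The male share of these genes went from 96.6% at 30 to 34 h to 70% at 54 to 58 h. Whether the 2 libraries of 30 to 34 h held animals of like age was not settled. At a limit of 2-fold it was 79.5% at 30 to 34 h, 53.5% at 48 to 52 h (3744 to 3260 genes) and 50.8% at 54 to 58 h (3913 to 3790). With library size only, the last 2 windows had 571 and 682 hermaphrodite-higher genes. At 30 to 34 h the highest male ratios were those of Y39B6A.9 (186 against 3.44 CPM), the collagen gene col-63 (89.8 against 1.25 CPM) and R01E6.5 (176 against 4.07 CPM), and the lowest those of Y47G6A.15 (4.52 against 198 CPM), F10B5.3 (1.57 against 38.1 CPM) and D1086.10 (0.261 against 12 CPM). At 36 to 40 h cut-3, Y74C10AR.2 and cutl-7 had 8216, 4533 and 3200 reads in males and 0, 3 and 1 reads in hermaphrodites, while Y47G6A.15, ttr-14 and D1086.10 had 1360, 133 and 83 CPM in hermaphrodites and at most 4.43 CPM in males. At 42 to 46 h F59B2.12, try-8 and srlf-18 had 1130, 428 and 189 CPM in males, and D1086.7, C35B1.4 and Y62H9A.3 had 64.2, 41.1 and 69.4 CPM in hermaphrodites. At 54 to 58 h F59B2.12 had 4470 CPM in males and 3.18 CPM in hermaphrodites, the largest ratio of this window, followed by clec-219 and F09C6.10. vit-2, vit-3 and ZK813.3 had the lowest ratios there.

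**Figure D2:**
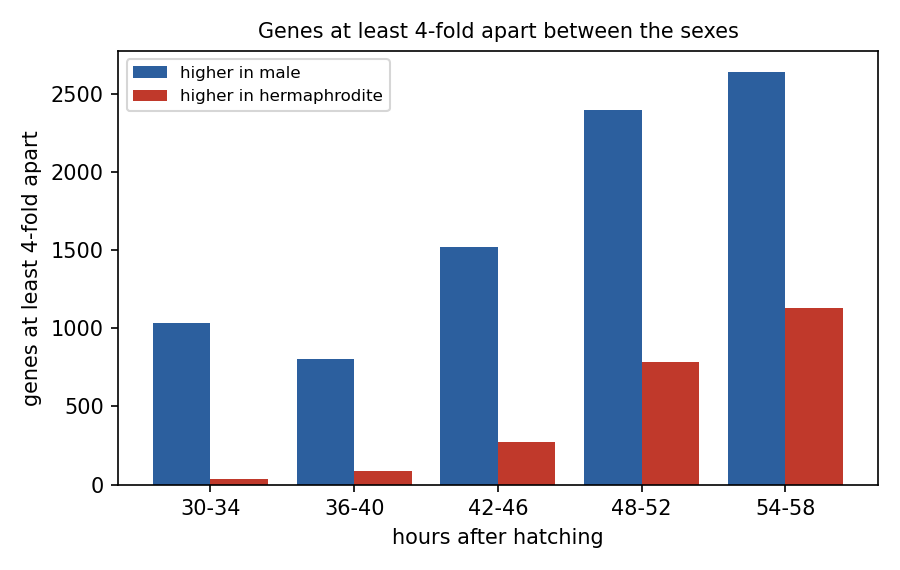
Number of genes at least 4-fold apart between the 2 libraries of each window (vertical axis, from 0) against hours after hatching, higher in male (blue bars) or in hermaphrodite (red bars). Hermaphrodite-higher genes went from 36 to 1132 and male-higher genes from 1032 to 2640, with 1 library per sex and window and no test.

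In young adults, the 2 windows of 48 to 52 h and 54 to 58 h served as 2 samples per sex of 1 labelled stage. Here 10012 of the 15924 genes passed an adjusted p of 0.05 in edgeR's test (n = 2 per sex), 5382 of them higher in males and 4630 higher in hermaphrodites. This split turned round without the male library of 54 to 58 h (3866 to 4106) and with at least 5 CPM in 5 libraries (3525 to 3671), and it was 6041 to 3756 with library size only. The count was 6236 when the male library of 48 to 52 h was left out and 6524 at an adjusted p of 0.01. The median log2 ratio of all genes was 0.31 towards males under TMM, 0.62 with library size only, 0.02 without the male library of 54 to 58 h, -0.02 with at least 5 CPM in 5 libraries and 0 without a filter. T26E3.6 was at least 541-fold, W02D7.12 at least 531-fold, K09C8.2 at least 448-fold, F40G9.7 at least 426-fold, C08E8.11 at least 410-fold and ZC204.17 at least 377-fold higher in males, all with 0 reads in both hermaphrodite libraries. F14H3.4 had 836 hermaphrodite reads and 1 male read (ratio 693, interval 124 to 27400) and ZK177.1 had 773 and 1 (ratio 641, with an upper bound of 25300). F40G12.11, F22E5.17 and F43D2.2 each had 2 male reads, with ratios of 395 (109 to 3270), 322 (88.8 to 2660) and 314 (86.5 to 2590), and ZK813.3 had a log2 ratio of -8.16 ± 0.98.

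All 34 major sperm protein genes and 34 of 36 other sperm genes were higher in males (1 of the 36 was lower), with spe-49 at a log2 ratio of 7.44 ± 0.53 and spe-42 at 7.09 ± 0.43 (adjusted p = 0.000573). All 6 yolk genes and 39 of 40 oocyte genes were lower in males, with vit-2 at -7.33 ± 0.79, vit-1 at -7.04 ± 0.95, nos-2 at -7.59 ± 0.35, cpg-3 at -6.33 ± 0.32 and perm-4 at -6.30 ± 0.37. Of 46 shared germline genes, 43 were lower in males and none higher (with library size only 39 were lower and 1 higher), with gld-1 at -3.46 ± 0.19 and xnd-1 at -2.87 ± 0.23. DNA replication genes were lower for 25 of 26, with rnr-1 at -4.11 ± 0.24 and mcm-2 at -3.88 ± 0.28. Ribosomal protein genes were lower for 74 of 75, with rps-2 at -2.31 ± 0.22. The exception was rpl-42, higher at 4.74 ± 0.83. Histone genes were lower for 26 of 34, with his-4 at -5.66 ± 0.49, and his-70 was again higher at 5.83 ± 0.48 (2 histone genes were higher with library size only). Muscle genes were higher for 18 of 24, with tni-3 at 4.68 ± 0.26 and the troponin T gene tnt-4 at 3.47 ± 0.82, the latter with an adjusted p of 0.104 without the male library of 48 to 52 h. Of 113 neuropeptide genes, 87 were higher and 2 lower (1 lower with library size only). Levels are shares of whole-animal reads. A higher muscle or neuropeptide share was thus not separated from a lower share of germline RNA. nlp-45 was at least 109-fold higher, and ins-31 had a log2 ratio of 9.80 ± 0.29. Of 152 C-type lectin genes, 100 were higher and 11 lower, with clec-103 at least 262-fold and clec-183 at least 243-fold higher. Of 23 sex determination genes, 17 were lower and 2 higher in males, with fog-3 at 5.44 ± 0.33 and sex-1 at -3.33 ± 0.59. Of 13 embryonic regulators, 7 were lower and 1 higher in males (2 higher with library size only). pes-10 had 151 hermaphrodite and 2 male reads (ratio 62.6, interval 17 to 521), and nhr-2 had a log2 ratio of -4.81 ± 0.98. Intestinal genes went both ways, with 6 of 24 higher and 2 lower (10 and 1 with library size only), among them the proteases cpr-3 (4.24 ± 0.31) and cpr-4 (3.32 ± 0.38) and the desaturase fat-7 (-2.77 ± 0.68). The call of fat-7 was lost without either male library.

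The next comparison asked how expression moved with time within each sex, as a linear slope per 6 h step. In hermaphrodites, 6 of 6 yolk, 39 of 40 oocyte, 45 of 46 germline and 25 of 26 DNA replication genes rose, and 13 of 17 structural cuticle collagen, 14 of 25 molting, 16 of 24 muscle and 60 of 113 neuropeptide genes fell. With library size only 4 yolk genes rose. None of these lists was called by camera with an estimated correlation (adjusted p = 0.349 for yolk, 0.263 for oocyte, 0.202 for germline and DNA replication, 0.535 for structural collagen, 0.366 for molting, 0.308 for muscle and 0.0532 for neuropeptide genes). A slope was called for 6016 genes in edgeR's test (n = 5 per sex), 3332 rising and 2684 falling. The split of rising to falling genes was 2583 to 3243 with library size only, 2560 to 3184 without the 30 to 34 h pair, 2321 to 854 without the 48 to 52 h pair and 1528 to 434 without the 54 to 58 h pair, so it depended on the scaling and on the libraries. The median slope of all genes was -0.15 per step under TMM, -0.10 with RLE factors and -0.23 with library size only, and -0.06 without the 30 to 34 h pair, -0.03 without the 54 to 58 h pair, -0.08 with at least 5 CPM in 5 libraries and -0.00997 without a filter. The count was 1962 without the 54 to 58 h pair, 3175 without the 48 to 52 h pair and 3807 with the 5 hermaphrodite libraries fitted alone.

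Slopes were ranked among called genes with a mean of at least 5 CPM. The steepest rises in hermaphrodites were those of clec-190 (log2 slope 3.26 ± 0.49 per step, adjusted p = 0.00204), vit-3 (2.94 ± 0.64), vit-2 (2.89 ± 0.98), vit-5 (2.85 ± 0.97), vit-4 (2.80 ± 0.78) and perm-4 (2.73 ± 0.68). The steepest falls were those of T05C1.3 (-3.13 ± 0.87), the cuticle collagen genes rol-6 (-2.97 ± 0.84), col-54 (-2.97 ± 0.35) and bli-1 (-2.96 ± 1.01), K02E11.10 (-2.94 ± 0.93) and lpr-1 (-2.90 ± 0.86). All 6 yolk genes, 39 of 40 oocyte genes, 45 of 46 germline genes and 25 of 26 DNA replication genes rose and none of them fell. Examples were perm-2 (2.72 ± 0.61), nos-2 (2.45 ± 0.61), the helicase gene glh-2 (1.20 ± 0.21), gld-1 (1.10 ± 0.13), mcm-5 (1.11 ± 0.11) and dut-1 (1.0 ± 0.12). Of 13 embryonic regulators, 6 rose and 2 fell (adjusted p = 0.308 with an estimated correlation), and sdz-28, pes-10 and hnd-1 had no reads in hermaphrodites before 48 to 52 h and 7.64, 7.37 and 3.65 CPM at 54 to 58 h. Histone genes rose for 13 and fell for 4 of 34, with his-68 at 1.21 ± 0.13 and his-70 at -1.19 ± 0.36.

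Falling groups in hermaphrodites included 13 of 17 structural cuticle collagen genes and 14 of 25 molting genes, with none rising. Examples were sqt-1 (-2.89 ± 0.87), qua-1 (-2.73 ± 0.85) and mlt-9 (-2.47 ± 0.72). These courses were not straight: sqt-1 had 332 CPM at 30 to 34 h, 1180 CPM at 36 to 40 h and 1.49 CPM at 54 to 58 h. Of all 137 col-named collagens 23 fell and 4 rose (adjusted p = 0.613 with an estimated correlation), and of 10 adult-stage collagens 1 fell. Muscle genes fell for 16 of 24 and rose for none, among them tnt-4 (-1.31 ± 0.22) and the pharyngeal myosin gene myo-1 (-1.08 ± 0.13). Neuropeptide genes fell for 60 of 113 and rose for none, with nlp-34 at -1.57 ± 0.34 and ins-26 at -1.43 ± 0.29. Intestinal genes fell for 12 of 24, with dod-6 at -1.01 ± 0.10. Levels are shares of whole-animal reads, and oocyte genes went from 10.8 to 387 CPM in hermaphrodites. The falls of muscle, neuropeptide and intestinal genes were thus not separated from dilution by rising germline transcripts. The adjusted p with an estimated correlation was 0.0532 for intestine. The geometric mean of the sperm genes in hermaphrodites was 2.62 CPM at 30 to 34 h, highest at 36 to 40 h, 11.3 CPM at 42 to 46 h, 4.87 CPM at 48 to 52 h and 1.54 CPM at 54 to 58 h, and of 36 members 31 had no called slope, 1 rose (2 with RLE factors) and 4 fell, among the latter spe-49 (-1.60 ± 0.38). The sex determination list rose for 11 and fell for 1 of 23 (adjusted p = 0.349 with an estimated correlation), with fog-3 at -1.08 ± 0.20 and fem-3 at 0.91 ± 0.11. Of 16 heterochronic regulators, 4 rose and 7 fell, with lin-42 at -1.30 ± 0.41 and lin-41 at 1.01 ± 0.21.

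In males, 94 genes had a called slope, 44 rising and 50 falling. The rise was led by C-type lectin genes: 12 of 152 rose and 2 fell (1 fell with library size only; adjusted p = 0.182 with an estimated correlation), with clec-134 at 3.72 ± 0.52, clec-94 at 3.09 ± 0.48 and clec-157 at 2.68 ± 0.32. C08E8.11 (3.26 ± 0.52), srlf-26 (2.91 ± 0.37) and the collagen gene col-95 (2.84 ± 0.45) also rose. Among called genes with a mean of at least 5 CPM, the steepest falls were those of igdb-3 (-4.03 ± 0.68), col-54 (-2.19 ± 0.34), the cadherin gene cdh-7 (-2.06 ± 0.32), cutl-16 (-1.70 ± 0.23), T19C4.1 (-1.61 ± 0.16) and C29E4.15 (-1.46 ± 0.18). The male tail gene lep-5 (-0.69 ± 0.09), the protease gene cpr-5 (-0.54 ± 0.08), the histone gene his-71 (-0.54 ± 0.08) and the ribosomal protein genes rpl-11.2 (-0.53 ± 0.06) and rpl-25.1 (-0.48 ± 0.08) were the list members called as falling among those lists. With RLE factors 1 ribosomal protein gene and no histone gene was called, and with library size only 2 male tail genes were. No major sperm protein or other sperm gene was called over all genes tested, with msp-81 at a slope of 0.71 ± 0.23 (adjusted p = 0.156). The geometric mean of each list in males was nonetheless higher at each later window. Major sperm protein genes had 16.5 CPM at 30 to 34 h and 108 CPM at 54 to 58 h. Other sperm genes had 18.8 and 72.1 CPM. The median slopes were 0.739 and 0.536 (camera adjusted p = 0.299 and 0.301 with an estimated correlation). The test of male slopes called 20.4% of simulated 8-fold changes, so the lack of calls does not show a level course. Of 75 ribosomal protein genes, 2 passed over all genes tested and 70 when p was adjusted over the list alone, with a median slope of -0.30. In camera the list had an adjusted p of 0.276 with an estimated correlation. The male count depended on the libraries and the fit: edgeR called no gene without the pair of 36 to 40 h, 48 to 52 h or 54 to 58 h (2741, 1739 and 1984 genes at an unadjusted p under 0.05), 59 without the 42 to 46 h pair, 28 without the male library of 54 to 58 h, and 1466 with the 5 male libraries fitted alone. With all libraries DESeq2 called 2007 and limma-voom 931, and 3084 genes had an unadjusted p under 0.05. The split of rising to falling genes was 64 to 32 with RLE factors, 11 to 97 without the 30 to 34 h pair and 26 to 2 without the male library of 54 to 58 h. Of the 50 genes falling in males, 42 also fell in hermaphrodites, where 8.43 would be shared by independent lists. Of the 44 rising in males, 1 rose in hermaphrodites, against 9.21. Both slopes came from 1 fit with 1 estimate of spread per gene, which ties the calls in the 2 sexes. The values for independent lists are thus a reference only.

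**Figure D3:**
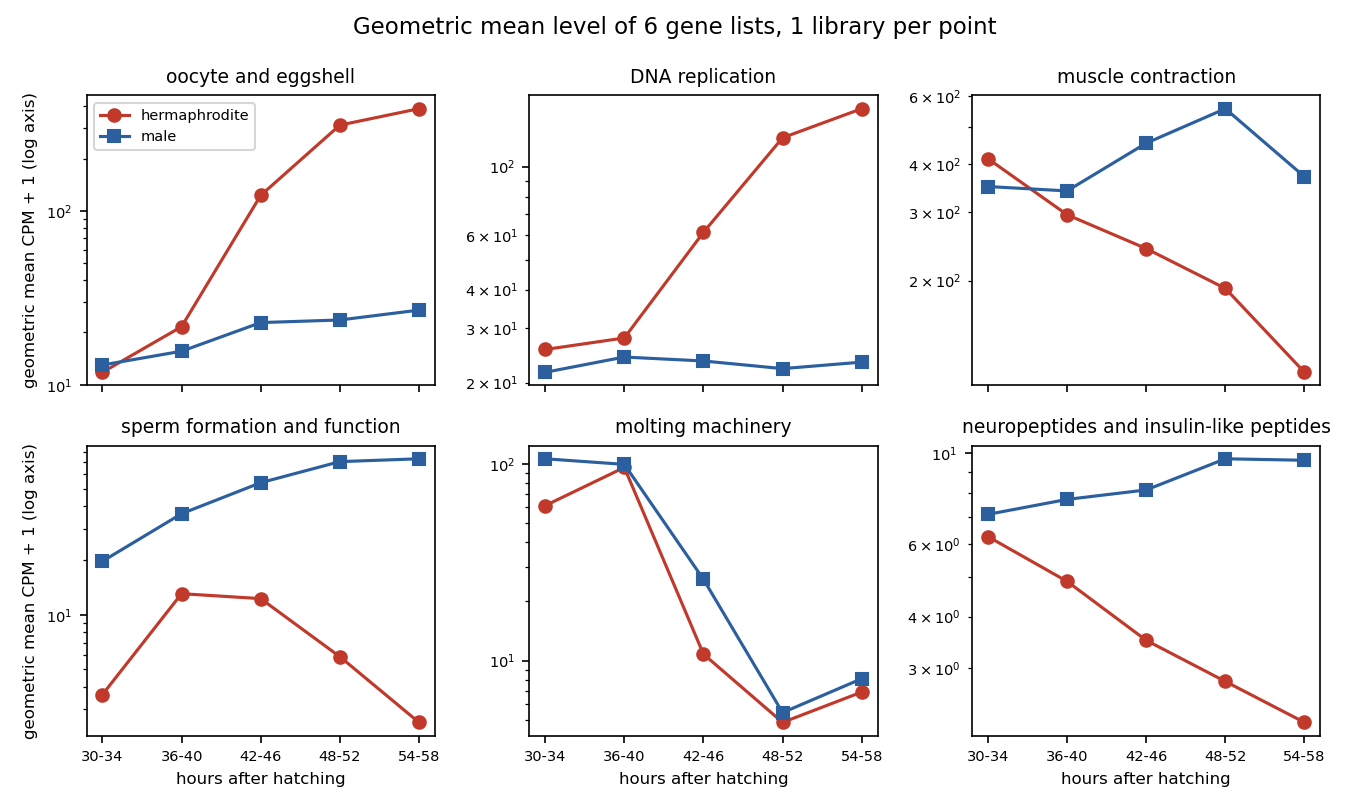
Geometric mean level (CPM + 1, log axis) of 6 gene lists against hours after hatching in hermaphrodites (red circles) and males (blue squares), with 1 library per point and no error bars. Oocyte genes went from 10.8 to 387 CPM and DNA replication genes from 24.6 to 153 CPM in hermaphrodites, muscle genes had 412 CPM at 30 to 34 h and 190 CPM at 48 to 52 h in hermaphrodites, and molting genes had 94.8 and 98.3 CPM at 36 to 40 h in hermaphrodites and males and 3.86 and 4.45 CPM at 48 to 52 h.

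Whether the 2 sexes differed in their time trend was tested directly, as a steady change of the male to hermaphrodite ratio. Towards males moved 15 of 24 muscle, 35 of 113 neuropeptide and 30 of 152 C-type lectin genes, and towards hermaphrodites 35 of 40 oocyte, 31 of 46 germline, 18 of 26 DNA replication and 24 of 34 histone genes. No list passed camera with an estimated correlation, where the lowest adjusted p was 0.0993, for neuropeptides. In edgeR's test 2519 genes were called, 892 with a ratio moving towards males and 1627 towards hermaphrodites. With library size only, 1408 were called and the split was 778 to 630. Without the 30 to 34 h pair 2132 were called with the split turned round, 1632 towards males and 500 towards hermaphrodites, and 968 of them were among the 2519. edgeR called no gene without the pair of 36 to 40 h, 42 to 46 h, 48 to 52 h or 54 to 58 h (5370, 5753, 4366 and 3443 genes at an unadjusted p under 0.05), none without the male library of 42 to 46 h (5687), none at an adjusted p of 0.01, and 3 without the male library of 54 to 58 h. DESeq2 called 5685 genes, limma-voom 3973, and 6081 had an unadjusted p under 0.05 with all libraries. For the genes named here the adjusted p lay between 0.0239 and 0.0451.

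Slope differences were ranked among called genes with a mean of at least 5 CPM. The largest changes towards males were those of F58F9.6 (4.92 ± 0.77 per step), Y47D7A.12 (4.22 ± 0.41), clec-103 (3.64 ± 0.84), F49F1.9 (3.27 ± 0.50), scl-25 (3.19 ± 0.69) and E02H9.9 (3.10 ± 0.61). The largest towards hermaphrodites were those of H31G24.1 (-6.80 ± 0.99), cut-3 (-3.59 ± 0.71), col-132 (-3.09 ± 0.77), sri-40 (-3.06 ± 0.59), H04M03.3 (-2.96 ± 0.71) and cutl-7 (-2.75 ± 0.47). H31G24.1, cut-3 and col-132 were highest in the male library of 36 to 40 h, at 75.5, 306 and 70.3 CPM, with no more than 0.572 CPM in any hermaphrodite library. Over all hermaphrodite libraries F58F9.6 and H31G24.1 had 2 reads each, F49F1.9 3, cutl-7 4, scl-25 5, col-132 7, cut-3 13, Y47D7A.12 14, clec-103 18 and E02H9.9 21, so the size of these 10 slope differences rests on few reads. Of 40 oocyte genes, 35 moved towards hermaphrodites and none towards males, with pos-1 at -1.64 ± 0.19, oma-2 at -1.57 ± 0.31 and cpg-3 at -1.55 ± 0.25. Germline genes did so for 31 of 46 (10 with library size only), with glh-2 at -0.91 ± 0.13 and gld-1 at -0.87 ± 0.11. DNA replication genes did so for 18 of 26, with rnr-2 at -1.05 ± 0.18 and rnr-1 at -1.02 ± 0.13, and histone genes for 24 of 34, with his-4 at -1.65 ± 0.22 and his-1 at -1.52 ± 0.21. Of 6 yolk genes, 1 was called (none with library size only), vit-3 at -1.55 ± 0.35. Of 75 ribosomal protein genes, 15 moved towards hermaphrodites (4 with library size only), with rpl-18 at -0.48 ± 0.09. The adjusted p with an estimated correlation was 0.271 for the oocyte and DNA replication lists, 0.253 for germline, 0.129 for histones, 0.489 for yolk and 0.363 for ribosomal proteins.

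Against the 30 lectin genes moving towards males, 3 went the other way. Examples of muscle and neuropeptide genes moving towards males were tnt-4 (1.40 ± 0.20), the pharyngeal myosin genes myo-2 (1.11 ± 0.12) and myo-1 (1.10 ± 0.11), ins-31 (1.64 ± 0.31) and flp-17 (1.40 ± 0.22). As shares of whole-animal reads, these moves were not separated from the rise of oocyte and germline genes in hermaphrodites. The adjusted p with an estimated correlation was 0.253 for muscle, 0.0993 for neuropeptides and 0.239 for lectins. Of 36 sperm genes, 3 moved towards males, spe-49 (1.74 ± 0.33), fer-1 (1.58 ± 0.22) and spe-4 (1.22 ± 0.23), and 1 towards hermaphrodites (none with library size only). Of 34 major sperm protein genes, 2 were called (1 with library size only), among them msp-78 (0.78 ± 0.12), and try-5 had 1.63 ± 0.36. The adjusted p with an estimated correlation was 0.489 for both sperm lists, 0.303 for male gonad secretion and 0.261 for intestine. Of 24 intestinal genes, 5 moved towards males, led by cpr-3 (1.42 ± 0.24). In hermaphrodites' favour moved 8 of 23 sex determination and dosage compensation genes (4 with library size only), led by sdc-1 (-0.97 ± 0.13; list adjusted p = 0.261 with an estimated correlation), 3 of 25 vulva and egg-laying genes, led by the EGF gene lin-3 (-1.0 ± 0.13), and 1 of 16 heterochronic genes, lin-41 (-1.09 ± 0.24; no heterochronic gene was called with library size only).

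X-linked genes were compared with autosomal genes because males carry 1 X chromosome and hermaphrodites carry 2. The median log2 male to hermaphrodite ratio of 2200 X-linked genes minus that of 13530 autosomal genes was -0.05 at 30 to 34 h, -0.03 at 36 to 40 h, 0.17 at 42 to 46 h, 0.27 at 48 to 52 h and 0.25 at 54 to 58 h. The mean was 0.12 ± 0.15 (SD, n = 5 time points), which did not differ from 0 in an exact two-sided sign-flip test (p = 0.25; with 5 time points no p under 0.05 can be reached).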

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

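The tests of hermaphrodite or male RNA in libraries of the other sex, of older males and of shared reads were chosen after the result was seen, and the splits of the samples and the embryonic list before. The gene sets for older males and shared reads were widened to all called sensory neuron genes and all sperm genes after values from smaller sets had been seen. Among 16 groups of library measures and 55 named genes tested for a lone value among 5, 2 and 3 stood apart, where chance gives about 1 in 20. The share of reads not aligned was 25.38% in the male library of 54 to 58 h (the other males 3.7% to 5.58%), and ribosomal RNA genes held 8.62% in that of 48 to 52 h (the others 4.62% to 5.23%). At 30 to 34 h the log2 ratio of male to hermaphrodite on CPM + 1 was 1.92 for cwp-1 (3.35 to 3.74 at the other windows), 0.40 for pkd-2 (4.14 to 5.52) and 3.68 for wrt-6 (1.24 to 1.94).

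Yolk transcripts were read in males, vit-2 at 70.8 CPM at 42 to 46 h and 90.8 CPM at 54 to 58 h. Hermaphrodite RNA in these libraries would bring other hermaphrodite-biased genes to a like share. The median of 20 such genes at 42 to 46 h was 3.43% of the hermaphrodite level of the same window, against 4.5% for yolk, and 2.06 times the yolk share when set against the hermaphrodite library of 48 to 52 h. It was 1.41 times the yolk share at 54 to 58 h, so some hermaphrodite RNA may account for the yolk reads, though ule-1, with 0 CPM in the male library of 42 to 46 h, goes against this. Yolk gene expression in males themselves stays open as an untested biological explanation.

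In the hermaphrodite library of 54 to 58 h her-1 had 7.16 CPM. The values argue against RNA of adult males as its source, since 20 male-biased genes lay at 0.00186 times the relative level of her-1. These genes were picked from the young adult pair of 48 to 52 h, so RNA of male embryos was not tested. Embryos carried by the hermaphrodites may contribute: the median change of 13 embryonic regulators from 48 to 52 h to 54 to 58 h (log2 0.435, 12 of 13 higher, 2 by 2-fold or more) lay at percentile 99.98 of 10000 random lists of matched expression, in 1 library per time. The random lists were matched for mean level only, and oocyte genes also rose between these libraries, from 311 to 387 CPM. The percentile thus cannot tell embryos from other rising hermaphrodite transcripts. It does not show that her-1 itself came from embryos, and expression in the adult stays open.

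Sperm transcripts stood higher in the male library at 30 to 34 h already. Older males in that library are not excluded: the 7 called sensory neuron genes had 0.387 times the share of their late level that 36 sperm genes had (median 9.57%, range 0% to 29.4%, against 24.7%, range 7.02% to 102%), and the ranges overlap. The male excess also held for sperm genes outside the near-identical major sperm protein family, which sharing of reads within that family could not raise. There 36 of 36 were higher in the male library, with a median log2 ratio of 2.47 (0.30 to 4.47). This could not test sharing within the family, whose single values stay uncertain. An earlier onset of sperm gene expression in males stays open as an untested biological explanation, with 1 library per sex.

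The sex difference in time trend was called for 2519 genes. Towards males the log2 slope differences per step were F58F9.6 4.92 (2 hermaphrodite reads in all), Y47D7A.12 4.22 (14), clec-103 3.64 (18), F49F1.9 3.27 (3), scl-25 3.19 (5), E02H9.9 3.10 (21), spe-49 1.74, ins-31 1.64, try-5 1.63, fer-1 1.58, cpr-3 1.42, tnt-4 1.40, flp-17 1.40, spe-4 1.22, myo-2 1.11, myo-1 1.10 and msp-78 0.78. Towards hermaphrodites they were H31G24.1 -6.80 (2 hermaphrodite reads), cut-3 -3.59 (13), col-132 -3.09 (7), sri-40 -3.06, H04M03.3 -2.96, cutl-7 -2.75 (4), his-4 -1.65, pos-1 -1.64, oma-2 -1.57, vit-3 -1.55, cpg-3 -1.55, his-1 -1.52, lin-41 -1.09, rnr-2 -1.05, rnr-1 -1.02, lin-3 -1.0, sdc-1 -0.97, glh-2 -0.91, gld-1 -0.87 and rpl-18 -0.48. Of 96 splits of the 10 libraries that could be fitted, 3 gave as many genes, the real one among them, and the highest other gave 4833. Among the 16 splits that part all 5 pairs, 3 gave as many, and with so few splits a share under 0.05 is out of reach. For the sex difference over 5 time points (3003), 3 of 100 splits gave as many, the real one among them. The others are the same fit with the groups exchanged, at 6713 genes. This points to a structure of the samples: that fit parts the sexes at the last 3 windows only. Among 12 splits parting all 5 pairs, 1 gave as many, the real one, and the highest other gave 4. The other splits swap the sexes at some windows, so any sex difference enters their residual spread. Their low counts thus cannot measure chance.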

How the results depend on the processing

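Leaving out ribosomal RNA and mitochondrial genes, and leaving out the male library of 42 to 46 h or of 54 to 58 h, were chosen after seeing the data, the rest before. No named gene that was checked reversed its direction under an alternative that tested it: 2347 of the values kept their side of the threshold and 773 lost the call. Genes named only at single windows were not checked, nor was msp-81. With at least 5 CPM in 5 libraries, only part of the 55 genes named for sex could be checked. Of these, 24 kept their side and 5 lost the call. The alternatives reuse the same libraries, so reversals were unlikely from the start. Among genes called both in the main fit and in an alternative, none changed sign. Genes that lost their call were not checked for sign, apart from these named genes. For the sex difference over 5 time points, DESeq2 called 5920 genes and limma-voom 5258, against 3003, and 1350 passed with at least 5 CPM in 5 libraries and 144 at an adjusted p of 0.01. Leaving out time points gave 118 to 3076, and the male library of 42 to 46 h 311 and that of 54 to 58 h 1881. Without time as a block, 3977 were called, of which 2534 were among the 3003. For the time trend in hermaphrodites (6016), 2931 passed at 0.01 and 3807 with that sex alone, and leaving out time points gave 1962 to 5744. For the time trend in males (94), DESeq2 called 2007, limma-voom 931, the stricter filter left 61, the males alone gave 1466, and edgeR called 0 at 0.01, where 3084 had an unadjusted p under 0.05. Leaving out time points or single male libraries gave 0 to 136. For the sex difference in time trend (2519), library size only gave 1408, DESeq2 5685, limma-voom 3973, no filter 1666 and edgeR at 0.01 gave 0 (6081 at an unadjusted p under 0.05). Leaving out time points gave 0 to 2132, and the fit without the block gave 2697. In young adults (10012), 6524 passed at 0.01, the block of time point gave 8750 and leaving out libraries gave 6236 to 9705. Fewer libraries and fewer genes account in part for lower counts by construction; the cause was not tested otherwise. At single windows, in order of time, a pseudocount of 5 CPM gave 340, 251, 680, 1874 and 2270 genes and a limit of 2-fold gave 1987, 2971, 4623, 7004 and 7703. With an estimated correlation, camera called 0 of the 26 lists for sex, 0 for each trend and 0 for their difference, against 18, 19, 18 and 17 with the preset correlation. Without ribosomal RNA and mitochondrial genes the 5 counts were 3003, 6002, 95, 2516 and 10005. The X to autosome difference was 0.125 with library size only and 0.0833 to 0.165 without 1 time point. The block, where it was the alternative, changed no other count by over 1.5 times. Depth limits genes of few reads. In the simulation, with 200 changed genes, a 2-fold change over the course was called as a slope for none. In the data, 5750 of the 6016 hermaphrodite slopes called were at least 2-fold over the course, so smaller changes were called there too.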

Other observations

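For other gene groups, most members were not called when the sexes were compared over 5 time points with edgeR. Of 118 chemoreceptor genes tested, 14 were higher and none lower, and 8 of these were among 21 srlf-named genes, for which membership in the family is uncertain. Of 39 hedgehog-related genes 5 were higher and none lower, and of 185 nuclear hormone receptor genes 5 were higher and none lower. Of 25 vulva and egg-laying genes 5 were higher and none lower, led by zmp-1 (log2 2.44 ± 0.59). Of 25 molting genes 5 were higher (3 with library size only) and none lower, with qua-1 at 1.85 ± 0.46, and of 16 heterochronic regulators 1 was, lin-29 at 1.76 ± 0.39. Structural collagens were higher for 5 and lower for 1 of 17, adult-stage collagens higher for 1 of 10 (none with library size only), and all col-named collagens higher for 10 and lower for 3 of 137 (none lower with library size only). Intestinal genes were higher for 1 and lower for 3 of 24 (none and 1 with library size only), and none of 13 embryonic regulators was called (lin-26, the most abundant, had -0.93 ± 0.59, adjusted p = 0.254). With an estimated correlation, the adjusted p in camera was 0.451 for chemoreceptors, hedgehog-related, embryonic, adult-stage collagen and male tail genes, and higher for the others.

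The courses of molting and collagen lists are given for both sexes without a test. Molting genes had a geometric mean of 60.3, 94.8, 9.8, 3.86 and 5.93 CPM over the 5 windows in hermaphrodites and 105, 98.3, 24.9, 4.45 and 7.1 CPM in males. Structural collagens had 173 CPM at 36 to 40 h and 2.18 CPM at 48 to 52 h in hermaphrodites, and 211 and 2.71 CPM in males. Adult-stage collagens had 5.84 CPM at 30 to 34 h and 148 CPM at 42 to 46 h in hermaphrodites, and 33.2 and 264 CPM in males.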
